A study of Mus musculus with 52 samples.

How the data were processed

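Messenger RNA of mouse EPSCs, mESCs and aggregates grown from treated EPSCs was sequenced in 52 libraries of 25 groups. Per the labels' protocols, total RNA was taken with an RNeasy kit, messenger RNA was caught on oligo-dT beads and fragmented, complementary DNA was primed with random hexamers, and paired reads came from an Illumina HiSeq instrument. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39, aligned to mm10 with STAR 2.7.10b and assigned to genes with featureCounts 2.0.6. The annotation, the strand setting and the treatment of read pairs are not given in the sources used here. The authors deposited raw counts per gene, whole numbers for 55291 genes that were neither scaled nor filtered as far as the values show. Every column of the table was joined to 1 sample. In 46 libraries from 66.8% to 80.5% of the counts from 1 to 10 were even, so the mates of a pair seem to have been counted separately there. In 6 libraries (EPSC libraries 3 and 4, P25 and P38) 40.7% to 42% were even, so pairs seem to have been counted once. Totals ran from 16.6 to 108 M counts, and no gene took more than 1.7% of a library.

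Libraries were grouped by the treatment in the labels. The 4 EPSC libraries were fitted as separate pairs, 1 pair per set of libraries, because the sets were submitted apart. Mean log2 CPM of the pairs correlated with r = 0.723, against 0.887 between EPSC libraries 3 and 4 and mESCs, and 3756 tested genes had no count in any of the 12 libraries of the first set. The spread between the libraries of a group was above counting error in every group, with chi-square per degree of freedom from 2.41 (the lowest) to 121 (CHIR). The SD of the log2 difference between a group's libraries was 0.56 in CHIR, 0.47 with PD0325901, 0.37 without XAV939 at S5 and 0.27 without Birabresib at S2.

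Genes were kept with the filterByExpr function of edgeR 4.0.16, which left 25056. Counts were scaled with TMM factors, and a single quasi-likelihood model with 1 mean per group was fitted to all libraries (edgeR, with limma 3.58.1, in R 4.3.3). Each of 27 comparisons was a contrast of group means tested with the quasi-likelihood F test, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. A gene was called changed at an adjusted p below 0.05 and an absolute log2 fold change of 1 or more. The SE of a log2 fold change was its size divided by the square root of F. The mESC and EPSC responses, the P25 and 2-day responses, and S2 and 2-day S1 were compared as differences of responses, each against the starting cells or EPSC libraries of its own set. The sum of single additions was the CHIR mean plus the effects of Elvitegravir, PD0325901 and CD1530 on the log2 scale. For a gene with no count in a group, a fold was given as a lower bound from a floor of 3 counts over the group. Symbols were matched to GENCODE M21 for coordinates, biotype and overlap with other genes, and 53186 matched.

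Gene lists for 27 themes were tested with camera on the normalized counts and the same contrasts, at an inter-gene correlation of 0.01 and again with the correlation estimated from the data. The p-values were adjusted over the 27 lists within each comparison, which made 729 tests. Correlations between libraries used log2 CPM with a prior count of 2. In each list, changed genes were counted with the p-values adjusted over all genes and with those adjusted over the list alone. Groups, comparisons, lists, thresholds and the rule for named genes were fixed before the data were examined.

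Genes were named by a rule with 4 parts. Part a took the 8 risen and 8 fallen genes with the largest log2 fold change in 6 comparisons (S1, treated mESCs, P25, S2, S3 and S5), among changed genes with a mean of 10 CPM or more in a compared group, without predicted genes. Part b took 4 and 4 in every other comparison. Part c took up to 3 changed members with the smallest adjusted p of each called list or of the list that stands for the agent. Part d was a fixed set of markers: Pou5f1, Sox2, Nanog, Zscan4c, Zscan4d, Zfp352, Cdx2, Gata3, Gata4, Gata6, Sox17, T, Mixl1, Otx2 and Fgf5. The rule allowed a part of b, c and d to be named in its order. Parts b and c are named in part, and the remaining genes of both are not reported here. Within part d the order was not followed, and which of these markers to give in a comparison was chosen after their values were seen, as was the choice of lists reported beside those that stand for an agent.

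Each comparison was repeated with RLE size factors, without the filter, with the Wald test of DESeq2 1.42.0, with the libraries of its own family alone, with the replicate number as a block, without each library in turn, and where it applied with the 4 EPSC libraries pooled or without adjustment for the set. After the data were seen, 6 further alternatives were added, which the closing part names. The test was tried on simulated data made from the group means and from the spread at each level of expression, with 100 genes planted at each fold. By adjusted p alone, edgeR recovered 94% at 2-fold and 100% at 4-fold in S1 against EPSCs. With the fold threshold as well, it called 1 of 24836 unchanged genes. At S5 without BMP4 it recovered 93% and 100% and called 4 unchanged genes, and in the mESC against EPSC difference 73% and 98% with 4 called. DESeq2 recovered 95% in S1 at 2-fold and 94% at S5 without BMP4, with 0 and 1 unchanged genes called. All recovered shares here use adjusted p alone, and all unchanged genes called had to pass the fold threshold too. Unchanged genes called by adjusted p alone were not counted. With the fold threshold, which a planted 2-fold sits on, edgeR called 54% in S1. It called 55% at S5 without BMP4 and 53% in the mESC against EPSC difference. Camera called a list of 20 genes planted at 1.5-fold, and 1 of 100 random lists had a p below 0.05. The simulated genes were drawn independently, so this cannot show how often camera calls lists of correlated genes falsely. Every simulated group was also given the same spread at a level of expression. The simulated rates may therefore not hold for groups with a wider spread, such as CHIR. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 prepared the annotation and drew the figures.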

Results

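Poly(A) RNA of mouse stem cells and of aggregates made from them was counted gene by gene in 52 libraries that fell into 25 groups. The starting cells were extended pluripotent stem cells (EPSCs) kept in LCDM medium, with 4 libraries, and embryonic stem cells (mESCs) kept in 2i/L medium, with 2 libraries. Every other group had n = 2 libraries. EPSCs were given a totipotency medium for 2 days (stage 1, S1) or over 25 or 38 passages (P25, P38), and mESCs were given the medium for 2 days. In other groups EPSCs received the GSK3 inhibitor CHIR-99021 (CHIR) for 2 days, alone or with 1 further compound. Aggregates were then followed at stages S2 and S3 in a medium called 4C-64C, and at S5 in a peri-implantation medium. At each of these stages 4 groups lacked 1 agent of the medium. S4 was not analysed here. Libraries held from 16.6 to 108 M counts, and 25056 of 55291 genes were tested. Values are mean CPM (counts scaled by TMM library size) ± SD of 2 libraries, and a log2 fold change is given with its standard error (SE). A gene "rose" or "fell" when its adjusted p was below 0.05 and its log2 fold change was at least 1 in size. Genes said to rise or fall most, and those said to follow them, were ranked by log2 fold change among changed genes with 10 CPM or more in a compared group, without predicted genes. Where a gene had no count in a group, its fold is a lower bound against a floor of 3 counts in that group. The floor covers counting error alone, and only where read pairs were counted once. In the 46 libraries whose mates seem to have been counted separately, 3 counts come from fewer pairs. There the floor does not fully cover counting error, and the stated bounds may be too high. Adjusted p-values measure the spread between these samples, because the labels do not say whether the 2 libraries of a group came from separate cultures. That spread was estimated for each gene over all groups together. An SE or adjusted p can therefore understate a wide spread within a compared group, which its SD shows. Coordinates are of mouse build mm10. The libraries came in a first set of 12, with EPSC libraries 1 and 2 and the 2-day EPSC treatments, and a second set of 40, with EPSC libraries 3 and 4. Each comparison used the EPSC libraries of its own set.

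The first question was what the totipotency medium did to EPSCs within 2 days. Zscan4c, which marks 2-cell embryos (chr 7, 11005745 to 11010547), had no count in EPSCs and reached 446 ± 24 CPM in S1 (n = 2), at least 12700-fold. Zscan4d (chr 7, 11161374 to 11166159) reached 464 ± 28 CPM, at least 13200-fold. Pramef25 reached 178 ± 3.1 CPM, at least 5090-fold, and the 2-cell gene Zfp352 (chr 4, 90218820 to 90225702) reached 53.1 ± 4.7 CPM, at least 1520-fold. Zscan4e (227 ± 23 CPM), Zscan4-ps3 (216 ± 9.9), Zscan4-ps2 (188 ± 12), Zscan4a (132 ± 8.3) and Usp17lb (116 ± 1.6) were also absent from EPSCs. Zscan4 copies and pseudogenes are close paralogs, so the split of reads among them is uncertain. Stra8, a retinoic acid target needed for meiotic entry (chr 6, 34920163 to 34939344), rose from 0.0912 ± 0.059 to 1100 ± 19 CPM (log2 fold change 13.48, SE 0.25). The pluripotency factor Pou5f1 (chr 17, 35506018 to 35510772) fell from 274 ± 5.1 to 10.5 ± 0.23 CPM (−4.70, SE 0.16), and Nanog (chr 6, 122707489 to 122714633) fell from 219 ± 6.9 to 42.7 ± 6.4 CPM (−2.36, SE 0.11).

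Tdh fell most in S1, from 313 ± 12 to 0.954 ± 0.034 CPM (−8.35, SE 0.14). It was followed by Olig2 (−7.75, SE 0.41), Nkx6-3 (−7.60, SE 0.54), Btla (−7.10, SE 0.42) and the ERK feedback gene Spry4, which went from 170 ± 5.5 to 1.64 ± 0.21 CPM (−6.71, SE 0.2). Tcl1 (−6.35, SE 0.25), Trh (−6.29, SE 0.27) and Tgm3 (−6.29, SE 0.46) came next. Of the other lineage genes, Otx2 fell to 0.48 ± 0.03 CPM (−5.72, SE 0.18) and T fell to 0.694 ± 0.2 CPM (−3.96, SE 0.26). Gata3 rose to 9.84 ± 0.24 CPM (4.75, SE 0.3), Sox17 to 7.9 ± 0.081 CPM (3.88, SE 0.24) and Cdx2 to 4.4 ± 0.074 CPM (2.55, SE 0.39). Sox2 had no count in any library of the first set, and 100% of its exonic bases lie inside another gene, so it could not be judged there. In all, 4673 genes rose and 2295 fell by the edgeR quasi-likelihood test.

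The gene lists gave the same comparison by function. Unless another number is given, the count adjusted over the list alone equals the count over all genes. List sizes include members with no count in any library of the first set, which could not pass there, among them 3 trophectoderm genes, 2 retinoic acid response genes and 1 each of the pluripotency, germline, cholesterol biosynthesis, interferon response and primitive streak lists. All 39 tested 2C-like totipotency genes rose in S1 (camera adjusted p = 1e-40; adjusted p = 1.4e-06 with an estimated correlation), with a median log2 fold change of 12.71, or 10.01 with 26 genes held at their bound. Of 20 germline genes 14 rose, Stra8, Sohlh2 (50.5 ± 3.1 CPM from 2.12 ± 0.0091) and Taf7l (71.8 ± 2.4 CPM from 1.69 ± 0.19) among them. Of 19 retinoic acid response genes 16 rose and 1 fell, with Stra6 at 79.6 ± 4.4 CPM and Dhrs3 at 54.9 ± 4 CPM. Of 27 trophectoderm genes 15 rose and 2 fell, with the keratins Krt18 (395 ± 87 CPM; 6.42, SE 0.16) and Krt8 (621 ± 120 CPM; 5.97, SE 0.17) among the risen. Of 22 core and naive pluripotency genes 18 fell, with Nr0b1 at 2.04 ± 0.23 CPM (−5.72, SE 0.16) and Fgf4 at 3.68 ± 0.57 CPM (−5.56, SE 0.17). Of 18 FGF and ERK target genes 12 fell and 2 rose, with Etv5 (−3.63, SE 0.1) and Dusp4 (−3.44, SE 0.12) among the fallen. Of 16 integrated stress response genes 9 fell and 1 rose, with Psat1 at 144 ± 9 CPM from 596 ± 11. Of 11 DNA methylation machinery genes 7 fell and 1 rose, with Tet1 (−3.51, SE 0.17) and Dnmt3b (−1.87, SE 0.08) among the fallen. Of 18 mitotic cell cycle genes 2 fell. Of 30 primitive and visceral endoderm genes 13 rose and 4 fell (camera adjusted p = 0.016), and the call was lost, adjusted p = 0.41 with an estimated correlation. Camera called 367 of 729 list tests over all comparisons, and 180 with an estimated correlation.

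**Figure D1:**
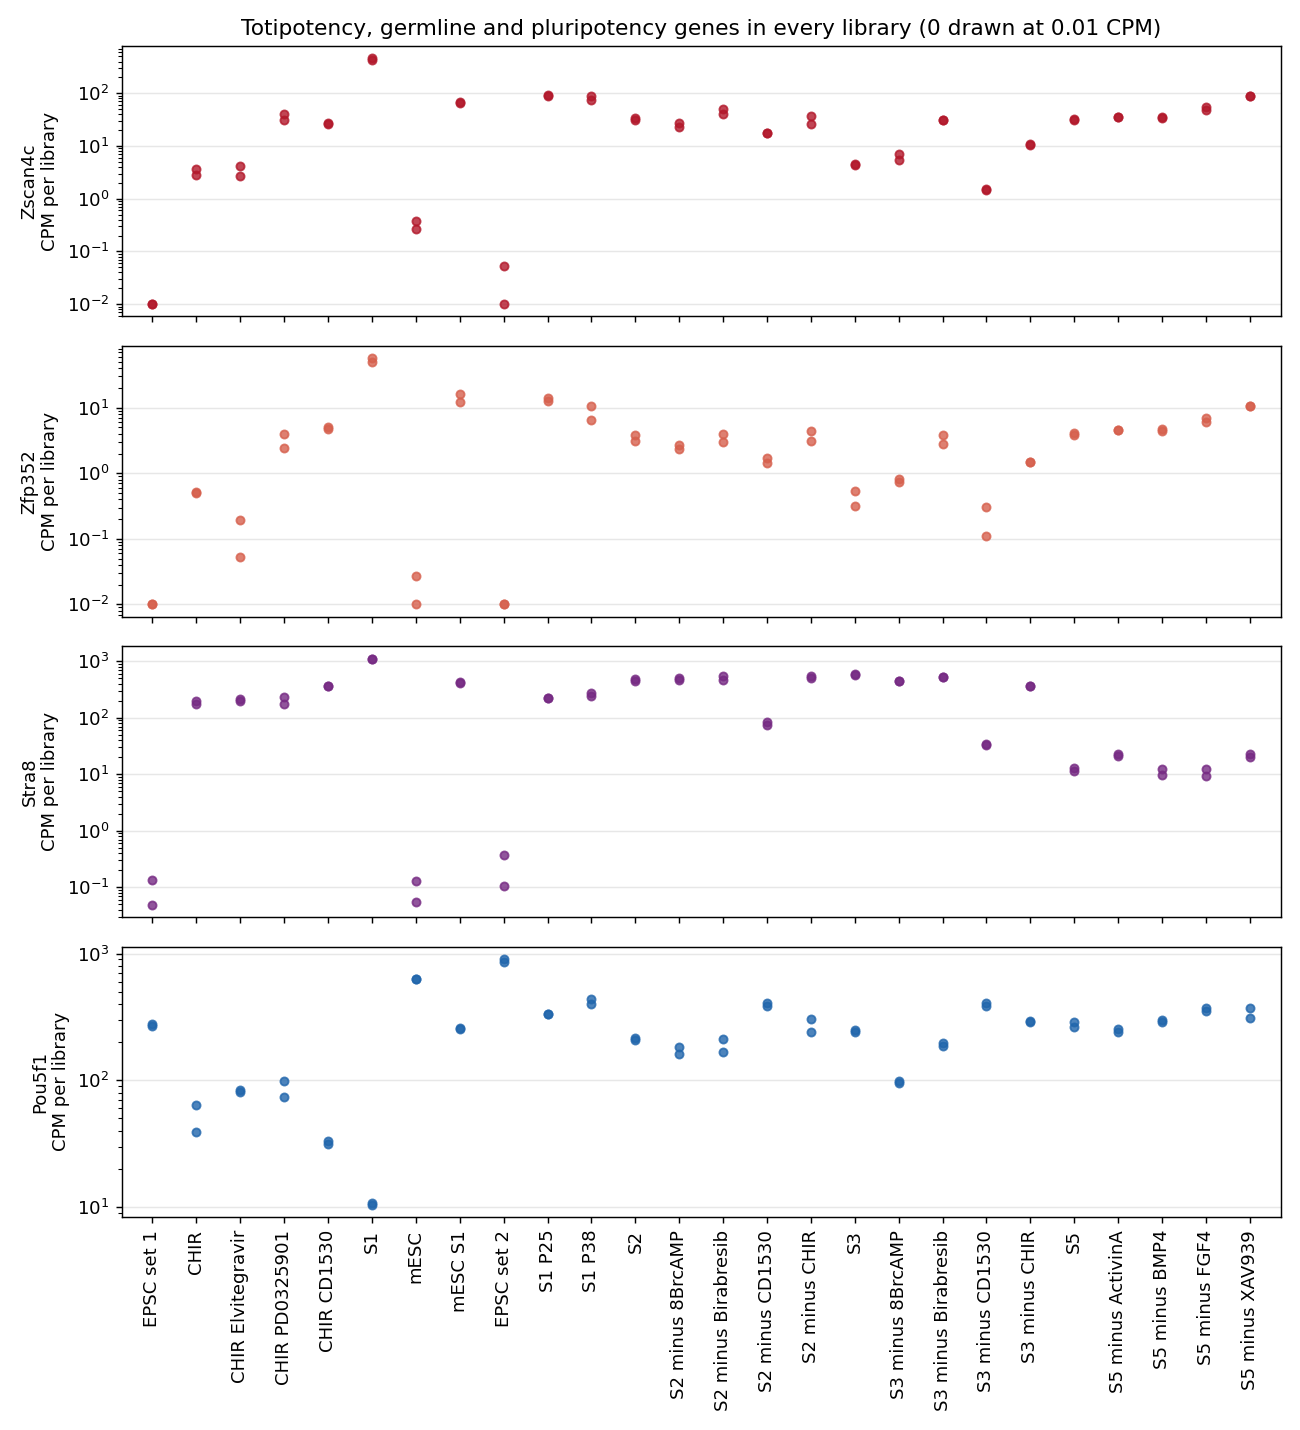
CPM of Zscan4c, Zfp352, Stra8 and Pou5f1 (log axis) in each of 52 libraries by group (horizontal axis), with 0 drawn at 0.01. Zscan4c averaged 446 CPM in S1 and had no count in EPSC libraries of that set.

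CHIR alone was compared with EPSCs to ask what the GSK3 inhibitor did without the other compounds. Stra8 rose to 186 ± 17 CPM (10.91, SE 0.24), Cubn, which encodes an endocytic receptor, rose from 0.234 ± 0.017 to 145 ± 2.6 CPM (9.26, SE 0.44), and Nxf7 rose from no count to 10.8 ± 2.3 CPM, at least 308-fold. Saa3 (−8.06, SE 0.32), Nkx6-3 (−7.00, SE 0.56), Trh (−6.91, SE 0.29) and the cholesterol exporter gene Abca1 (−6.80, SE 0.25) fell most. Zscan4c reached 3.2 ± 0.54 CPM, at least 91.4-fold above EPSCs, and Zscan4d reached 3.11 ± 0.97 CPM, at least 88.8-fold. Pou5f1 fell to 51.6 ± 18 CPM (−2.40, SE 0.14) and Nanog to 21.2 ± 0.71 CPM (−3.36, SE 0.11). Of the 39 2C-like genes 30 rose and 1 fell (31 rose adjusted over the list alone), with a median of 6.34, or 3.85 with 27 genes at their bound. Of the pluripotency genes 17 fell, Esrrb (−4.15, SE 0.13), Nr0b1 (−4.88, SE 0.16) and Zfp42 (−3.36, SE 0.11) among them, and 12 germline genes rose, including Sohlh2 (3.08, SE 0.12). Of 18 Wnt target genes 7 fell, 2 rose and 9 did not pass, with Sp5 at 3.12 ± 1.2 CPM from 46.6 ± 2.9 (−3.85, SE 0.2), Notum (−4.47, SE 0.31) and Axin2 at 28.1 ± 11 CPM from 117 ± 0.68 (−2.05, SE 0.16). The base medium of the CHIR arm is not given in the sources used here. LCDM by its published formula contains CHIR, so neither the Wnt target genes nor other genes here compare CHIR with its absence. Of 18 feeder fibroblast genes 9 fell and 1 rose, and the call was lost, adjusted p = 0.1 with an estimated correlation. In all, 2921 genes rose and 1752 fell, 4673 together, or 7564 with the 4 EPSC libraries pooled.

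Elvitegravir, an HIV integrase inhibitor, was added to CHIR to ask for its own share. Zscan4c stood at 3.43 ± 0.96 CPM against 3.2 ± 0.54 with CHIR alone (0.13, SE 0.19, adjusted p = 0.89), and Nanog at 21.3 ± 2.3 against 21.2 ± 0.71 CPM (0.00, SE 0.11). Pou5f1 stood at 82 ± 2.3 against 51.6 ± 18 CPM (0.66, SE 0.14, adjusted p = 0.069). By edgeR 1 gene rose, Fam214b (1.06, adjusted p = 0.025), and 1 fell, Bmp2 (−2.58, adjusted p = 0.019). Both genes were chosen for naming after their values were seen. DESeq2 gave 43 changed genes, and 4529 genes had an unadjusted p below 0.05. With the replicate number as a block edgeR gave 68, and with no low-count filter 142. It gave 0 with halved counts, with its newer option, with the libraries of the additives alone, and without CHIR and PD0325901 libraries 2. Without CHIR library 1 the count was 1562, and without CHIR library 2 or either Elvitegravir library it was 0, so neither Fam214b nor Bmp2 passed there. Pou5f1 passed without CHIR library 1 (1.12, adjusted p = 6.7e-07). No gene of the lists called by camera rose or fell, and none of the calls stayed, the Wnt target list having an adjusted p = 0.15 with an estimated correlation.

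PD0325901, a MEK inhibitor, was added to CHIR to ask what blocking ERK signalling contributed. Zscan4d rose from 3.11 ± 0.97 to 40.8 ± 14 CPM (3.74, SE 0.2), with Zscan4-ps3 (3.67, SE 0.23), Zscan4f (3.58, SE 0.29) and Zscan4c (36.3 ± 6.7 CPM; 3.51, SE 0.17) next. Cubn fell from 145 ± 2.6 to 0.725 ± 0.29 CPM (−7.86, SE 0.38), the basement membrane gene Lama1 (−4.79, SE 0.22) and Srgn (−4.40, SE 0.28) fell, and the endoderm factor Gata6 (chr 18, 11052064 to 11085635) fell from 11.5 ± 0.37 to 0.569 ± 0.038 CPM (−4.30, SE 0.19). Nanog rose to 103 ± 23 CPM (2.28, SE 0.11) and Klf2 to 102 ± 18 CPM (1.76, SE 0.13). Of the 2C-like genes 31 rose, or 36 adjusted over the list alone, with a median of 2.86 (adjusted p = 5.5e-09 with an estimated correlation). Of the endoderm genes 16 fell and 2 rose, Dab2 (−4.01, SE 0.14) among the fallen, and 8 pluripotency genes rose. Of the FGF and ERK target genes 6 fell and 12 did not pass, with Dusp4 (−1.48, SE 0.11) and Egr1 (−3.06, SE 0.27) among the fallen. Of the feeder fibroblast genes 4 rose, and this call was lost too, adjusted p = 0.29 with an estimated correlation. In all, 819 genes rose and 310 fell.

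CD1530, an agonist of the retinoic acid receptor gamma, was added to CHIR to ask what retinoid signalling contributed. Cyp26a1, which encodes a retinoic acid hydroxylase (chr 19, 37697798 to 37701536), rose from 2.37 ± 0.87 to 228 ± 9.6 CPM (6.53, SE 0.26), followed by Hoxb8 (6.49, SE 0.36), Aqp8 (6.47, SE 0.43) and Cyp26c1 (5.71, SE 0.43). Otx2 fell from 11.8 ± 1.3 to 0.0948 ± 0.018 CPM (−6.94, SE 0.26), with Nphs1 (−6.71, SE 0.37), Tdgf1 (−6.26, SE 0.19) and Lef1 (−5.75, SE 0.15) next. The endoderm factors Gata4 (216 ± 5.8 CPM; 4.02, SE 0.17), Gata6 (140 ± 1.9 CPM; 3.60, SE 0.14) and Sox17 (99.3 ± 2.4 CPM; 5.06, SE 0.2) rose, Sparc rose to 2440 ± 58 CPM (3.76, SE 0.12) and Col4a2 to 1220 ± 20 CPM (4.86, SE 0.17). Zscan4c rose to 26.8 ± 0.74 CPM (3.08, SE 0.17) and Nanog fell to 2.23 ± 0.041 CPM (−3.25, SE 0.13). Of the endoderm genes 23 rose and 2 fell, of the retinoic acid response genes 13 rose, Meis1 (4.51, SE 0.23) and Stra6 (4.04, SE 0.21) among them, and of the 2C-like genes 35 rose and 1 fell. Of 16 BMP target genes 10 rose (adjusted p = 0.0015 with an estimated correlation), and 10 formative and primed epiblast genes fell (adjusted p = 0.015 with an estimated correlation). In all, 2441 genes rose and 1731 fell.

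The S1 medium was then set against the sum of the single additions on the log2 scale, to ask which genes answered to the whole medium more or less than the parts add up to. Gjb2, a gap junction gene, stood at 69.5 ± 1.3 CPM in S1 and at 3.17 ± 0.49 with CHIR, 2.74 ± 0.16 with Elvitegravir, 3.03 ± 0.42 with PD0325901 and 1.51 ± 0.22 with CD1530, and so exceeded the sum (5.80, SE 0.49). Stmn4 exceeded it too (4.47, SE 1.08). Aqp8 (−5.64, SE 1.56), Pth1r (−5.14, SE 0.45), Tdh (−5.08, SE 0.23) and Amn (−4.93, SE 0.48) lay below it. Zscan4c did not pass (0.41, SE 0.35, adjusted p = 0.59). Pou5f1 lay below the sum (−3.03, SE 0.29) and Nanog above it (1.97, SE 0.23). Of the endoderm genes 16 lay below the sum, or 19 adjusted over the list alone (median −1.58), with Lamb1 at 199 ± 2.2 CPM in S1 and 2240 ± 4.1 with CD1530. Of the germline genes 5 lay above and 1 below (8 above adjusted over the list alone), Meioc (3.10, SE 0.35), Taf7l (1.59, SE 0.27) and Stra8 (1.30, SE 0.24) among them. Of 17 p53 target genes 7 lay above, Pmaip1 (1.68, SE 0.2) included, and 1 below (2 below adjusted over the list alone), with an adjusted p = 0.044 with an estimated correlation. In all 691 genes exceeded the sum and 1020 lay below it. Without CHIR library 2 the total was 628 and without CHIR library 1 it was 4657. Without PD0325901 library 1 it was 1058 and without library 2 it was 2807. It was 490 with the libraries of the additives fitted alone, where neither Aqp8 (adjusted p = 0.053) nor Stra8 (adjusted p = 0.054) passed, and 870 without CHIR and PD0325901 libraries 2 together, where Aqp8 did not pass (adjusted p = 0.43). Stmn4 did not pass without CHIR library 1 (adjusted p = 0.12), nor did Aqp8 without PD0325901 library 2 (adjusted p = 0.12) or without CHIR library 2 (adjusted p = 0.087). The labels do not state that S1 medium holds exactly these 4 compounds.

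mESCs given the totipotency medium for 2 days were compared with untreated mESCs to ask whether the response depends on the starting cell. Zscan4b rose from no count to 16 ± 2.2 CPM, at least 358-fold, and Stra8 rose from 0.0927 ± 0.054 to 420 ± 5.5 CPM (12.15, SE 0.25). Pramef25 (15.6 ± 0.78 CPM) and Zfp352 (14.2 ± 2.7 CPM), each with 1 count in mESCs, Zscan4d (35.7 ± 0.63 CPM; 9.16, SE 0.34), Halr1 (8.49, SE 0.3), Eif4a3l1 (8.45, SE 0.38) and Zscan4e (8.37, SE 0.44) followed. Zscan4c rose from 0.321 ± 0.084 to 67.5 ± 1.8 CPM (7.68, SE 0.24). Pgc (−6.85, SE 0.4), Kcna2 (−5.82, SE 0.7), Serpina3n (−5.70, SE 0.61), Trpm1 (−5.66, SE 0.27), Abhd12b (−5.45, SE 0.65), Ly6g6e (−5.19, SE 0.49), Ap1m2 (−4.93, SE 0.25) and Ptx3 (−4.89, SE 0.41) fell most, and all exonic bases of Ptx3 lie inside another gene. Pou5f1 fell from 629 ± 1.8 to 255 ± 2.1 CPM (−1.30, SE 0.14). Nanog stood at 738 ± 4.6 against 539 ± 4.9 CPM (0.45, SE 0.1) and Sox2 at 361 ± 8 against 450 ± 2.1 CPM (−0.32, SE 0.09), short of the fold threshold.

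In mESCs, 36 of the 2C-like genes rose and 1 fell, with a median of 7.16, or 6.38 with 9 genes at their bound (adjusted p = 7.7e-06 with an estimated correlation). Of the retinoic acid response genes 16 rose and 1 fell, Stra6 (8.33, SE 0.3) included, and of the germline genes 13 rose and 2 fell, Sohlh2 (4.45, SE 0.11) included. Of the trophectoderm genes 19 rose and 2 fell, with the imprinted gene Peg10 at 2250 ± 42 CPM from 49.8 ± 2.7. Of 20 cholesterol biosynthesis genes 7 rose (adjusted p = 0.017 with an estimated correlation). Of the pluripotency genes 10 fell and Dppa2 rose (2.14, SE 0.1), with Nr0b1 (−2.71, SE 0.14) among the fallen, and this call was lost, adjusted p = 0.22 with an estimated correlation. In all 3561 genes rose and 2070 fell.

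The mESC response was then tested against the EPSC response. Spry4 fell in EPSCs from 170 ± 5.5 to 1.64 ± 0.21 CPM, yet stood at 1.02 ± 0.13 in mESCs and 4.76 ± 0.44 CPM after treatment (difference 8.94, SE 0.3). Its level in untreated mESCs was already low, so it had little room to fall there. Vrtn, Olig2 and Wnt8a also had higher responses in mESCs, with EPSC levels of 23.4 ± 0.83, 42 ± 0.0032 and 8.1 ± 0.94 CPM and no count in mESCs, so no size is given, and Olig2 did not pass without library 1 of the treated mESCs (adjusted p = 1). Il20ra rose in EPSCs from 2 counts to 37.4 ± 2.8 CPM and stood at 0.0401 ± 0.057 CPM in treated mESCs, a lower response. Krt8 reached 621 ± 120 CPM in S1 from EPSCs and 10.8 ± 0.65 CPM from mESCs (−4.49, SE 0.22). Pou5f1 (3.40, SE 0.2), Nanog (2.81, SE 0.15), Fgf4 (4.42, SE 0.2) and Klf2 (3.94, SE 0.18) had higher responses in mESCs, and Klf2 stood at 287 ± 9.2 CPM in treated mESCs and 21.3 ± 0.48 in S1. Of the pluripotency genes 18 had a higher response in mESCs (median 2; adjusted p = 0.002 with an estimated correlation), as did 10 FGF and ERK target genes while 2 had a lower one. Of the 2C-like genes 22 responded less in mESCs (23 adjusted over the list alone), but the list call was lost, adjusted p = 0.13 with an estimated correlation. Among feeder fibroblast genes 6 responded less in mESCs and none more (1 more adjusted over the list alone), a call lost as well, adjusted p = 0.4 with an estimated correlation. Over all genes, 2181 had a higher and 2497 a lower response in mESCs. The responses correlated with a Pearson r of 0.49 over 25056 genes, which are not independent replicates (0.36 with no low-count filter), and with 0.56 over 19631 genes measured in both sets. Both responses shared 2027 risen genes, where 664 would be shared if they were independent, and 615 fallen genes against 190, while 300 genes went in opposite directions. Cell type, starting medium (2i/L or LCDM) and library set are not separable in this comparison.

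S1 cells at passage 25 were compared with the EPSC libraries of their own set, to ask what long culture in the medium keeps. Tmprss2 (60.1 ± 4.5 CPM, at least 746-fold), Car4 (44.4 ± 6, at least 551-fold), Pramef25 (41.8 ± 4, at least 519-fold) and Zscan4f (37.4 ± 0.64, at least 465-fold) rose from no count. So did Zscan4-ps1 (32.3 ± 0.6 CPM), Usp17le (28.1 ± 1.5), Crygd (22.1 ± 1.8) and Aurkc (19.6 ± 0.95). Zscan4c rose from 1 count in EPSCs to 91.7 ± 3.4 CPM, and Stra8 rose to 222 ± 1.6 CPM (9.83, SE 0.24). Nkx6-3 (−7.45, SE 0.63), Trpm1 (−6.50, SE 0.31), Mmp3 (−6.49, SE 0.44), Trh (−6.20, SE 0.27), Pgc (−5.09, SE 0.39), Nkx6-2 (−4.92, SE 0.32), Grem1 (−4.87, SE 0.44) and Serpina3n (−4.83, SE 0.64) fell most. Pou5f1 fell from 888 ± 30 to 334 ± 0.0054 CPM (−1.41, SE 0.14) and Sox2 from 518 ± 17 to 249 ± 7.3 CPM (−1.06, SE 0.1), while Nanog did not pass (0.24, SE 0.1, adjusted p = 0.062). With the 4 EPSC libraries pooled Pou5f1 did not pass (−0.80). Among the 2C-like genes 37 rose, with a median of 9.64, or 7.08 with 20 genes at their bound. Of the germline genes 17 rose (18 adjusted over the list alone), of the retinoic acid response genes 18 rose, and of the trophectoderm genes 19 rose and 2 fell, Krt18 at 323 ± 13 CPM among the risen. Of 25 imprinted genes 13 rose and 2 fell, with H19 at 7170 ± 44 CPM from 6.15 ± 0.22 (10.19, SE 0.35) and Peg10 at 5010 ± 43 CPM from 204 ± 25. Of the pluripotency genes 13 fell and 1 rose (adjusted p = 0.038 with an estimated correlation). Of the feeder fibroblast genes 4 rose and 3 fell, or 4 adjusted over the list alone, and the list was not called. In all 3315 genes rose and 1379 fell.

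At passage 38 the same comparison gave Tmprss2 at 55.6 ± 3.4 CPM, at least 690-fold above EPSCs, Zscan4c at 81 ± 9.8 CPM, Stra8 at 259 ± 20 CPM (10.05, SE 0.24) and H19 at 4690 ± 760 CPM (9.57, SE 0.34). Pou5f1 fell to 421 ± 26 CPM (−1.08, SE 0.14), but not with the 4 EPSC libraries pooled (−0.46). Of the 2C-like genes 37 rose, and of 17 oocyte and maternal genes 4 rose, Tle6 (2.61, SE 0.16) included, a call that was lost, adjusted p = 0.12 with an estimated correlation. Of the feeder fibroblast genes 5 fell and 2 rose (6 fell adjusted over the list alone), Dcn (−3.33, SE 0.27) among the fallen, a call that was lost as well, adjusted p = 0.22 with an estimated correlation. In all 2969 genes rose and 1505 fell. Passage 38 was then compared with passage 25 to ask whether the state drifts. Zscan4c did not pass (−0.18, SE 0.14, adjusted p = 0.72) and neither did Pou5f1 (0.33, SE 0.14, adjusted p = 0.26). Cd22 rose (1.06, SE 0.27), and Hoxb1, a retinoic acid response gene, fell from 13.6 ± 0.82 to 4.65 ± 0.82 CPM (−1.54, SE 0.25), with Armh4 (−1.41, SE 0.16) and Espn (−1.37, SE 0.2). Rhox5 had no count at passage 38, and its 46.4 ± 65 CPM at passage 25 came from 1 library, without which, P25 library 2, it did not pass (adjusted p = 0.74). Of 24 glycolysis and hypoxia genes 3 fell, Ldha from 1920 ± 7.4 to 949 ± 210 CPM (−1.02, SE 0.13) and Ndrg1 (−1.34, SE 0.2) among them (adjusted p = 0.00071 with an estimated correlation), and of the feeder fibroblast genes 2 fell, Col1a2 (−1.19, SE 0.16) and Col1a1 (−1.26, SE 0.21) (adjusted p = 0.00071 with an estimated correlation). In all 8 genes rose and 77 fell. The total was 85, and it was 45 without P25 library 1, 52 without P25 library 2, 145 with halved counts of the other libraries and 192 with these libraries and their EPSCs fitted alone. Cd22 did not pass without P25 library 1 (adjusted p = 0.25) or 2 (adjusted p = 0.16) or P38 library 1 (adjusted p = 0.33). Col1a2 (−0.88) and Col1a1 (−0.89) did not pass without P38 library 1, nor did Ldha (−0.80) and Ndrg1 (−0.97) without P38 library 2.

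The responses at passage 25 and after 2 days were compared through the EPSC libraries of each set, to ask how long culture differs from the first exposure. Pou5f1 went from 888 ± 30 to 334 ± 0.0054 CPM at passage 25 and from 274 ± 5.1 to 10.5 ± 0.23 CPM in 2 days, a difference of 3.29 (SE 0.2). Fkbp6 stood at 50.5 ± 0.3 CPM at passage 25 and 1.32 ± 0.081 in 2-day S1 (7.15, SE 0.67). Xlr5a, Nlrp4c and Car4 had higher responses as well, at 13.7 ± 1.8, 11.5 ± 0.79 and 44.4 ± 6 CPM at passage 25 and 1.58 ± 0.091, 1.36 ± 0.3 and 25.3 ± 3.4 in 2-day S1. They had no count in EPSC libraries 3 and 4, so no size is given, and their symbols may have been counted differently in the sets. Car4 did not pass without EPSC library 1 (adjusted p = 0.067), 3 (adjusted p = 0.087) or 4 (adjusted p = 0.086), nor with edgeR's newer option (adjusted p = 0.11). With the 4 EPSC libraries pooled or with no set adjustment it fell short of the fold threshold (0.81). Zscan4d stood at 65.8 ± 1.4 and 464 ± 28 CPM, a lower response at passage 25 (adjusted p = 0.0018), while Zscan4c at 91.7 ± 3.4 and 446 ± 24 CPM did not pass (adjusted p = 0.13), though it did with EPSC libraries pooled or with no set adjustment (−2.28). Neither gene had a count in EPSC libraries 1 and 2. In EPSC libraries 3 and 4 Zscan4d averaged 0.107 and Zscan4c 0.0267 CPM, so their different calls may rest on counts near the floor. Of the pluripotency genes 13 had a higher response at passage 25 (median 2.22), Fgf4 (4.31, SE 0.21) and Klf2 (3.37, SE 0.17) among them, and Nanog did as well (2.60, SE 0.15). Of the glycolysis and hypoxia genes 20 had a higher response, Ldha at 1920 ± 7.4 against 293 ± 75 CPM, and of 19 interferon response genes 5 had a lower one, Oasl2 at 7.74 ± 0.15 against 28.3 ± 0.12 CPM. In all 1193 genes had a higher and 1138 a lower response, 2331 together, against 7517 with EPSC libraries pooled and 8037 with no set adjustment.

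S2 aggregates were compared with 2-day S1 in the same way, to ask what 1 day of 4C-64C medium did. Pakap (8.19, SE 0.3), Fam220a (7.26, SE 0.27) and Septin2 (5.92, SE 0.19) came out high, with EPSC libraries 3 and 4 at 0.699 ± 0.38, 0.188 ± 0.037 and 3.68 ± 1.1 CPM. With no set adjustment S2 and S1 lay close in these genes (0.56, 0.09 and −0.07), so the high values rest on the difference between the EPSC pairs. EPSC libraries 3 and 4 are among the 6 whose pairs seem to have been counted once, unlike S2, so a difference in their counting stays open. The mesoderm factor Evx1 stood at 13.1 ± 1 CPM in S2 and 0.0928 ± 0.029 in S1 (8.01, SE 0.62), and Enpp2 (6.48, SE 0.54) and Gad1 (5.84, SE 0.38) came out high too. So did Dlx3 (7.78 ± 0.24 CPM in S2, 14.2 ± 0.67 in S1) and Crygc (25.9 ± 0.32 and 13.2 ± 2), which had no count in EPSC libraries 3 and 4. With EPSC libraries pooled or with no set adjustment Pakap (0.56), Fam220a (0.09) and Crygc (0.97) fell short of the fold threshold, and Septin2 (−0.07) and Dlx3 (−0.86) had the opposite sign. Among genes measured in both sets Tdh (5.74, SE 0.16), Foxn4 (5.46, SE 0.65), Etv4 (4.86, SE 0.25) and Nr0b1 (4.79, SE 0.2) followed. Naaladl2 fell from 25.7 ± 2.7 CPM in S1 to no count in S2, Fam227b from 25.4 ± 2.5 CPM to no count, and Zscan4d from 464 ± 28 to 27.3 ± 3.5 CPM. Nav3 fell too (−8.36, SE 0.87). So did Wnt10b (11.6 ± 1.9 to 1.18 ± 0.033 CPM), Stmn4 (22.2 ± 4.5 to 0.957 ± 0.19), Zscan4b (91.3 ± 20 to 7.88 ± 0.61) and Phf11a (12.7 ± 0.97 to 0.619 ± 0.14), which had no count in EPSC libraries 1 and 2. Nanog stood at 465 ± 20 CPM in S2 and 42.7 ± 6.4 in S1 (2.52, SE 0.15), and Pou5f1 at 212 ± 6.3 and 10.5 ± 0.23 CPM (2.64, SE 0.2). The S2 labels name S1 cell aggregates but not their time in S1 medium. In the S1 cells of the second set Nanog stood at 492 (P25) and 654 CPM (P38), and Pou5f1 at 334 and 421 CPM. Neither mean was therefore higher in S2 than in these S1 cells, which were not tested against S2. Crygc did not pass without EPSC library 1 (adjusted p = 0.053), 2 (adjusted p = 0.056), 3 or 4 (each adjusted p = 0.11), nor with edgeR's newer option (adjusted p = 0.14). Fam227b did not pass without EPSC library 4 (adjusted p = 1). Stmn4 did not pass without EPSC library 1 (adjusted p = 0.074), 2 (adjusted p = 0.067) or 4 (adjusted p = 1), nor without S1 library 1 or S2 library 2 (each adjusted p = 0.051) or with the newer option (adjusted p = 0.15).

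Of the Wnt target genes 10 rose in S2, or 11 adjusted over the list alone, with Lef1 (3.26, SE 0.17), Sp5 at 91.4 ± 3 against 15.7 ± 1.4 CPM (3.60, SE 0.24) and Cdx1 at 546 ± 20 against 73 ± 1.8 CPM (3.05, SE 0.24). Cdx2, a trophectoderm and caudal factor, rose to 22.4 ± 1.2 CPM (3.24, SE 0.72). Of the pluripotency genes 13 rose and 1 fell, and of the FGF and ERK target genes 8 rose and 2 fell. Of the interferon response genes 14 fell (median −2.89), with Oasl2 at 4.72 ± 0.13 against 28.3 ± 0.12 CPM, and of the feeder fibroblast genes 12 fell, Col6a2 (−3.75, SE 0.27) included. Of 23 primitive streak and mesoderm genes 8 rose and 1 fell, and the call was lost, adjusted p = 0.38 with an estimated correlation. In all 1319 genes rose and 2055 fell, 3374 together, against 8892 with EPSC libraries pooled and 9393 with no set adjustment. S2 and S1 were in different library sets, and these log2 values rest on the EPSC libraries of each. No list was tested between S2 and the S1 cells of its own set (P25 and P38). These list counts therefore cannot tell which changes came within the day in 4C-64C medium.

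S3 was compared with S2 to ask what the second day in 4C-64C medium did. Fosb (6.86, SE 0.76) and Fos (33.5 ± 1.1 CPM from 1.78 ± 0.13; 4.23, SE 0.3) rose most, with Aqp8 (4.06, SE 0.4), Cubn (2.73, SE 0.34), Hoxb5os (2.63, SE 0.37), Sox17 (23.4 ± 1.2 CPM; 2.53, SE 0.19), Csf3r (2.50, SE 0.29) and Gadd45g (2.14, SE 0.17). Hoxb5os is antisense to a Hox gene, and reads of the opposite strand may have been counted. Zscan4e (−3.57, SE 0.26), Zscan4d (27.3 ± 3.5 to 2.41 ± 0.064 CPM; −3.50, SE 0.2), Zscan4-ps3 (−3.24, SE 0.22), Foxn4 (−3.15, SE 0.39), mt-Nd4 (1930 ± 150 to 229 ± 29 CPM; −3.07, SE 0.23), Zscan4a (−3.04, SE 0.27), Zscan4f (−2.93, SE 0.28) and Zscan4c (33.2 ± 1.9 to 4.45 ± 0.22 CPM; −2.90, SE 0.16) fell most. Pou5f1 (0.22, SE 0.14, adjusted p = 0.31) and Nanog (−0.18, SE 0.1, adjusted p = 0.25) did not pass. Of the 2C-like genes 31 fell (median −2.26; adjusted p = 6.2e-07 with an estimated correlation). Of the endoderm genes 13 rose and 1 fell, Pdgfra (2.13, SE 0.15) and Gata4 (1.99, SE 0.18) among the risen, and 6 trophectoderm genes rose (7 adjusted over the list alone). In the cAMP and CREB target list Fos and Fosb rose, so its median of −0.03 and its mean of 0.73 differ in sign, and the upward call was lost, adjusted p = 0.17 with an estimated correlation. Of the feeder fibroblast genes 7 fell, Postn (−1.28, SE 0.19), Col6a2 (−1.46, SE 0.22) and Col3a1 (−1.49, SE 0.23) among them (adjusted p = 0.049 with an estimated correlation), and of the mitotic cell cycle genes 2 fell, Plk1 (−1.04, SE 0.21) and Mki67 (−1.01, SE 0.22) (adjusted p = 4.4e-05 with an estimated correlation). In all 477 genes rose and 845 fell. With the mean of all 5 S3 groups in place of the S3 libraries Zscan4c fell by 2.30 and Sox17 rose by 2.10, but mt-Nd4 (−0.72), Col6a2 (−0.96), Plk1 (−0.35) and Mki67 (−0.46) did not pass and Csf3r had the opposite sign (−0.06). Mki67 also fell short of the fold threshold without S3 library 1 (−0.93), and at −0.99 with RLE size factors, with DESeq2 and with its own family alone.

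S5 was compared with S3 to ask what the peri-implantation medium did, across an interval that includes S4. Afp, a visceral endoderm gene, rose from no count to 72.6 ± 33 CPM, at least 2130-fold, Cer1 to 27.5 ± 8.3 CPM, at least 806-fold, Spink1 to 18.1 ± 6.1 CPM, at least 529-fold, and Habp2 to 13.5 ± 0.3 CPM, at least 397-fold. Other genes share 63.8% of the exonic bases of Afp. Pga5 (361 ± 55 CPM; 10.93, SE 0.33), Apoa1 (10.38, SE 0.56), Ttr (60.2 ± 16 CPM; 10.28, SE 0.48) and Irs4 (10.18, SE 0.38) followed. Tlx2 (−9.61, SE 0.4), Csf3r (18.2 ± 1.3 CPM to 2 counts), Sp5 (116 ± 8.4 to 0.405 ± 0.072 CPM; −8.15, SE 0.26), Bhmt (−7.87, SE 0.43), Cdx1 (378 ± 21 to 2.28 ± 0.35 CPM; −7.37, SE 0.22), Hoxb5os (−6.56, SE 0.5), Ffar3 (−6.09, SE 0.4) and Notum (−5.66, SE 0.21) fell most. Nanog fell from 410 ± 26 to 139 ± 4.6 CPM (−1.56, SE 0.11), and Pou5f1 did not pass (0.17, SE 0.14, adjusted p = 0.34). Zscan4c rose from 4.45 ± 0.22 to 31.7 ± 1.3 CPM (2.83, SE 0.16).

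Of the endoderm genes 23 rose in S5 (median 3.39), with Lefty1 (7.24, SE 0.22), Gata4 at 232 ± 57 CPM (3.98, SE 0.17), Dab2 at 718 ± 140 CPM (4.81, SE 0.14) and Lrp2 at 2480 ± 750 CPM (5.83, SE 0.22). Of the formative epiblast genes 12 rose, Fgf5 to 69.8 ± 6 CPM (9.22, SE 0.37), Otx2 to 126 ± 11 CPM (4.18, SE 0.15) and Dnmt3b to 879 ± 22 CPM (3.05, SE 0.09). Of 13 Nodal and Activin target genes 10 rose, Lefty2 to 296 ± 52 CPM (5.39, SE 0.15) included. Of the glycolysis and hypoxia genes 21 rose, with Ldha at 2390 ± 230 CPM from 156 ± 7.2 (3.94, SE 0.14). Of the Wnt target genes 13 fell and 2 rose (median −2.64), of the retinoic acid response genes 12 fell and 3 rose, and Stra8 fell to 12.1 ± 1.2 CPM (−5.58, SE 0.15). Of the 2C-like genes 31 rose and 2 fell (median 2.95). The DNA methylation machinery list had a median of −0.06 and a mean of 0.80, and its upward call was lost, adjusted p = 0.17 with an estimated correlation. In all 3535 genes rose and 2129 fell.

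**Figure D2:**
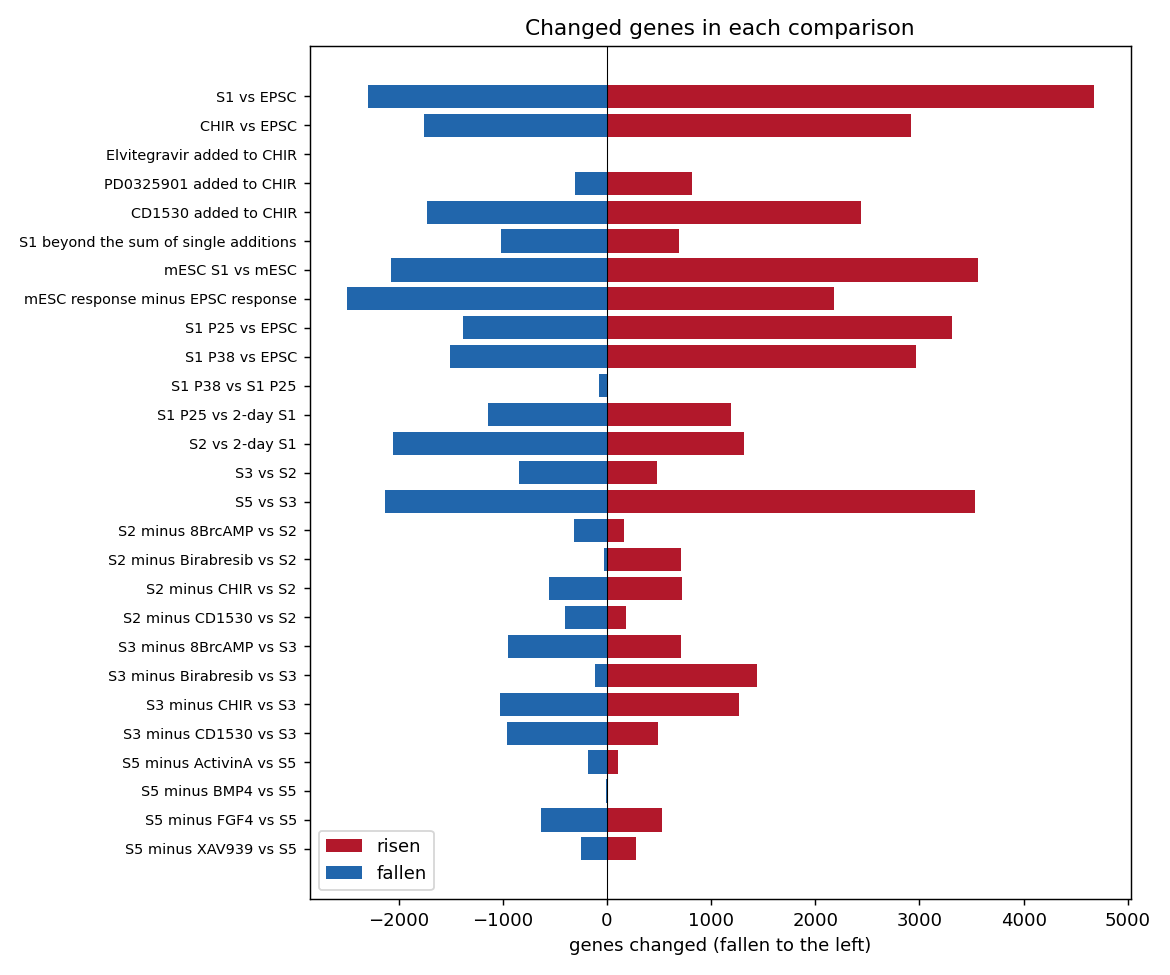
Genes risen (to the right) and fallen (to the left) in each of 27 comparisons, as numbers of genes. S1 against EPSC had 4673 risen and 2295 fallen genes.

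**Figure D3:**
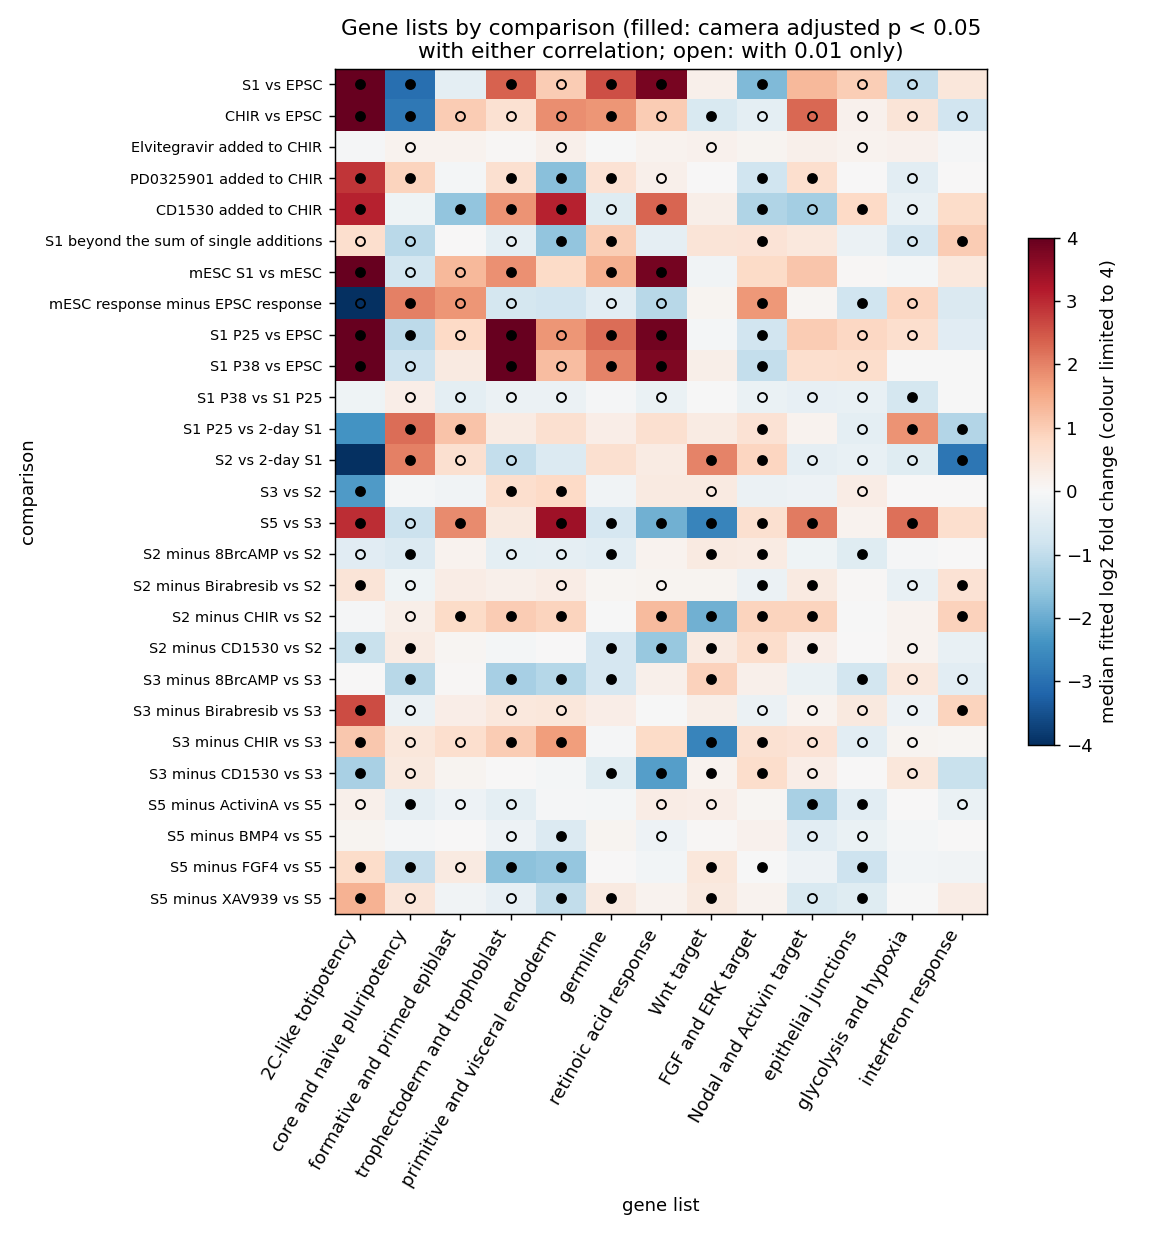
Median fitted log2 fold change (colour) of 13 gene lists (horizontal axis) in 27 comparisons (vertical axis). Filled dots mark lists called with an estimated correlation, and open dots mark calls at a correlation of 0.01 alone. The 2C-like list had a median of 12.71 in S1.

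Aggregates without 8Br-cAMP, a cAMP analogue, were compared with the full medium to ask for the part of cAMP signalling. At S2 Bcl2 fell from 144 ± 5.5 to 17.9 ± 1 CPM (−3.01, SE 0.15), and of 17 cAMP and CREB target genes 4 fell, Pde4d (−1.48, SE 0.13) and Nr4a1 (−1.52, SE 0.15) among them, and 1 rose, with a median of −0.08 and an adjusted p = 0.013 with an estimated correlation. Dnmt3l rose (2.08, SE 0.15), and 3 Wnt target genes rose, Lef1 (1.62, SE 0.12) included. Gata6 fell to 6.71 ± 0.26 CPM (−1.53, SE 0.14), and 5 of 20 epithelial junctions genes fell, Cldn4 (−1.33, SE 0.12) and Krt18 (−1.34, SE 0.12) among them. Zscan4c did not pass (−0.39, SE 0.14, adjusted p = 0.11). The S3 libraries stood apart from all 4 S3 omission groups, with 42 genes risen and 4 fallen in every omission and with mitochondrial genes at 0.78% to 0.9% of counts, against 1.58% to 3.43% in the other libraries of S2, S3 and S5. A change at S3 against these libraries can therefore not be laid to the omitted agent alone. At S3 Pcdh18 (3.29, SE 0.29), mt-Nd4 (3.04, SE 0.23) and mt-Nd2 (315 ± 43 to 2040 ± 8.3 CPM) rose, but mt-Nd4 (0.13) and mt-Nd2 (0.11) did not pass against the other 3 S3 omission groups. Bcl2 fell to 12.7 ± 0.54 CPM (−3.83, SE 0.15), Aqp8 (−6.47, SE 0.51) and Csf3r (−5.51, SE 0.37) fell, 7 cAMP and CREB target genes fell, and Gata6 fell from 43.8 ± 3 to 8.49 ± 1.3 CPM (−2.36, SE 0.14). Among endoderm genes 15 fell and 1 rose, of the trophectoderm genes 11 fell and 1 rose, Krt18 (−1.95, SE 0.12) among the fallen, and of the pluripotency genes 13 fell and 1 rose. Of the feeder fibroblast genes 3 rose, a call that was lost, adjusted p = 0.38 with an estimated correlation. Cdx2 rose from 18.6 ± 2.1 to 99.5 ± 6.3 CPM (2.42, SE 0.29) and Lef1 to 85.8 ± 7.1 CPM (2.45, SE 0.12). In all 161 genes rose and 320 fell at S2, 481 together or 756 against the other 3 omission groups, and 709 rose and 951 fell at S3.

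Birabresib, an inhibitor of BET bromodomain proteins, was left out to ask for the part of BET inhibition. At S2 the Nodal inhibitor gene Lefty2 rose from 8.16 ± 1.3 to 64.4 ± 5.9 CPM (2.98, SE 0.14), Nphs1 (2.29, SE 0.3), Atg9b (2.15, SE 0.19) and the interferon response gene Oasl2 (20.8 ± 1.9 CPM; 2.14, SE 0.21) rose, and Zic2 fell (−1.28, SE 0.13). Of 9 BET inhibitor reporter genes 1 fell, H1f2 (−1.18, SE 0.18), with an adjusted p = 0.014 with an estimated correlation, and 6 interferon response genes rose. Among the 2C-like genes 3 rose, or 4 adjusted over the list alone. Zscan4c stood at 45 ± 6.3 against 33.2 ± 1.9 CPM (0.44, SE 0.14), below the fold threshold. At S3 Zscan4e (3.35, SE 0.26) and Htr5a (3.09, SE 0.49) rose, Zscan4d rose from 2.41 ± 0.064 to 19.7 ± 2.1 CPM (3.03, SE 0.19) and Zscan4c from 4.45 ± 0.22 to 31.3 ± 0.091 CPM (2.82, SE 0.16), and 34 of the 2C-like genes rose (median 2.62; adjusted p = 5.7e-08 with an estimated correlation). Against the other 3 S3 omission groups Zscan4c rose by 2.76, and the fall of Txnip (−0.97) did not pass. Sox21 (−1.88, SE 0.15), Txnip (−1.39, SE 0.17) and H1f2 (−1.38, SE 0.18) fell at S3, and all exonic bases of Txnip lie inside another gene. Of the interferon response genes 8 rose at S3, Ifitm3 (1.68, SE 0.15) and Oasl2 (2.29, SE 0.21) included. The feeder fibroblast list was called upward at S2, where 1 of its genes rose, and at S3, where 2 rose, and both calls were lost, adjusted p = 0.087 and adjusted p = 0.34 with an estimated correlation. In all 714 genes rose and 32 fell at S2, 746 together, with 366 without S2 library 1 and 437 without S2 library 2. Without S2 library 1 H1f2 fell short of the fold threshold at S2 (−0.99). At S3 1441 rose and 115 fell, 1556 together. Against the other 3 omission groups the totals were 2093 at S2 and 2891 at S3.

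CHIR was left out to ask for the part of Wnt signalling. At S2 the Wnt target genes Sp5 (91.4 ± 3 to 1.53 ± 0.041 CPM; −5.90, SE 0.22), Axin2 (320 ± 21 to 24.3 ± 1.9 CPM; −3.72, SE 0.17) and Lef1 (−3.44, SE 0.15) fell, 11 of the list in all (median −1.93; adjusted p = 4.9e-09 with an estimated correlation). Cdx2 fell from 22.4 ± 1.2 to 3.99 ± 1.1 CPM (−2.49, SE 0.32), Dusp4 (2.21, SE 0.12) and Dusp6 (2.42, SE 0.13) rose among 8 FGF and ERK target genes, and Lefty2 rose to 88.9 ± 6.1 CPM (3.44, SE 0.14). Among endoderm genes 12 rose and 1 fell, Sox7 (3.50, SE 0.22) included, and of the trophectoderm genes 13 rose and 1 fell. Of the neural and surface ectoderm genes 4 rose and 1 fell (adjusted p = 0.043 with an estimated correlation), and of 12 blood and endothelium genes 5 rose and 1 fell (adjusted p = 0.04 with an estimated correlation). At S3 Sp5 fell to 0.265 ± 0.3 CPM (−8.76, SE 0.28) and Axin2 from 453 ± 20 to 14.9 ± 0.54 CPM (−4.93, SE 0.18), with 13 Wnt target genes fallen and 2 risen. Shisa3 rose (6.11, SE 0.51), Gata4 rose from 14.7 ± 0.5 to 67.7 ± 0.66 CPM (2.21, SE 0.16), Dab2 rose to 124 ± 9.8 CPM (2.29, SE 0.13), Lrp2 rose to 359 ± 6 CPM (3.04, SE 0.2), Cdx2 fell to 2.01 ± 0.0072 CPM (−3.21, SE 0.34), and 19 endoderm genes rose and 1 fell. Zscan4c rose to 10.7 ± 0.43 CPM (1.26, SE 0.16), and 15 of the 2C-like genes rose (17 adjusted over the list alone), but Zscan4c did not pass against the other 3 S3 omission groups (0.68). The feeder fibroblast list was called upward at S2 with 1 gene risen, and the call was lost, adjusted p = 0.26 with an estimated correlation. In all 716 genes rose and 555 fell at S2, and 1264 rose and 1030 fell at S3.

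CD1530 was left out to ask for the part of retinoid signalling. At S2 Stra8 fell from 467 ± 15 to 78.5 ± 6.7 CPM (−2.57, SE 0.13), Foxn4 (−3.43, SE 0.4), Dhrs3 (−2.39, SE 0.21) and Aqp3 (−2.10, SE 0.19) fell, and 13 retinoic acid response genes fell, or 14 adjusted over the list alone (median −1.51; adjusted p = 1.2e-05 with an estimated correlation). The primitive streak genes T (chr 17, 8434423 to 8442496; 5 ± 0.14 to 31.1 ± 1.5 CPM; 2.64, SE 0.23) and Mixl1 (2.66, SE 0.3) rose, as did Btla (3.17, SE 0.37), and 6 FGF and ERK target genes rose, Dusp4 (1.66, SE 0.11) and Spry4 (2.25, SE 0.17) included, though Dusp4 did not pass against the other 3 S2 omission groups (0.97). Of the primitive streak genes 5 rose and 1 fell, and the list call was lost, adjusted p = 0.071 with an estimated correlation. Of the 2C-like genes 7 fell, or 9 adjusted over the list alone, Zfp352 (−1.15, SE 0.27) included, which did not pass without S2 library 2 (adjusted p = 0.08) or without the S2 omission library 2 (adjusted p = 0.098). At S3 Stra8 fell from 578 ± 19 to 33.4 ± 0.48 CPM (−4.11, SE 0.14), Crabp2 (−3.24, SE 0.31) and Dhrs3 (−3.02, SE 0.2) fell, and 15 retinoic acid response genes fell (median −2.21). At S3 mt-Nd4 rose (229 ± 29 to 2060 ± 140 CPM; 3.17, SE 0.23), but it did not pass against the other 3 S3 omission groups (0.30). T rose to 35.6 ± 2.2 CPM (3.10, SE 0.23), Prss56 rose (3.04, SE 0.48), Bmp4 rose to 50.1 ± 1 CPM (2.98, SE 0.18) and Spry4 rose to 87.4 ± 5.6 CPM (2.71, SE 0.17). Zscan4c fell to 1.49 ± 0.061 CPM (−1.58, SE 0.19), and 18 of the 2C-like genes fell (20 adjusted over the list alone). At S3 also 3 feeder fibroblast genes fell, and this call was lost, adjusted p = 0.2 with an estimated correlation. In all 180 genes rose and 403 fell at S2, 583 together or 1125 against the other 3 omission groups, and 493 rose and 957 fell at S3.

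**Figure D4:**
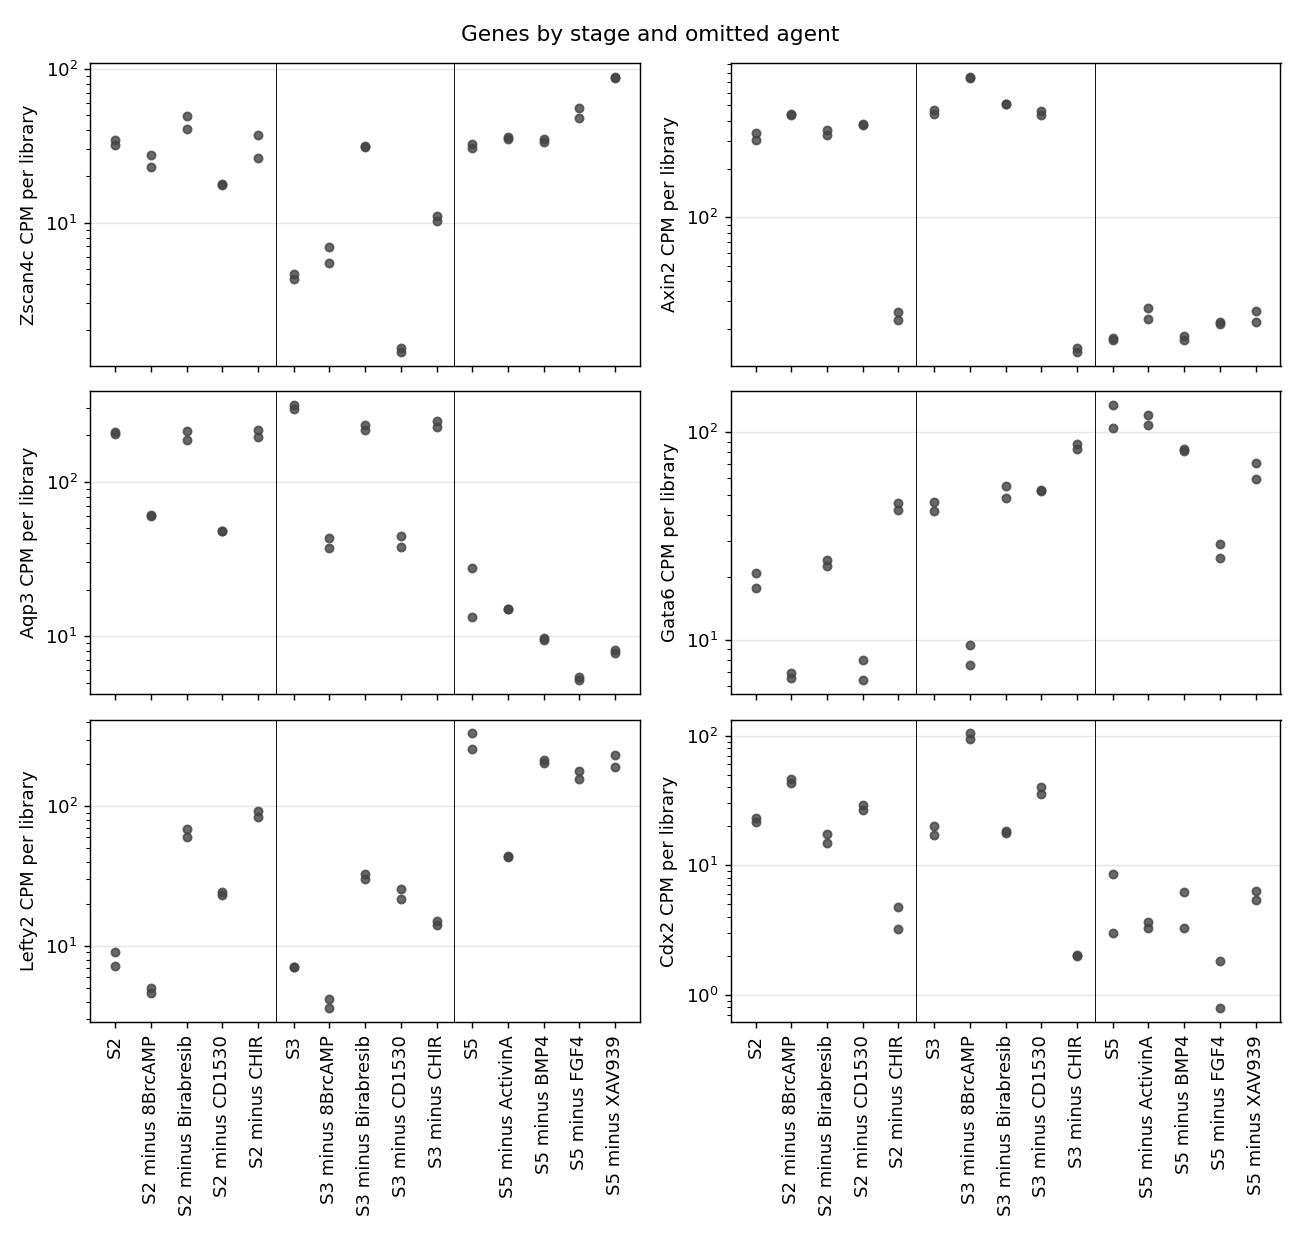
CPM of Zscan4c, Axin2, Aqp3, Gata6, Lefty2 and Cdx2 (log axis) in each library of S2, S3 and S5 by omitted agent (horizontal axis). Axin2 averaged 320 CPM at S2 and 24.3 CPM without CHIR.

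At S5, Activin A was left out to ask for the part of Activin signalling. Lefty2 fell from 296 ± 52 to 43.8 ± 0.53 CPM (−2.76, SE 0.13), Cer1 fell from 27.5 ± 8.3 to 2.82 ± 0.42 CPM (−3.29, SE 0.45), and Otx2 fell to 43.4 ± 4.6 CPM (−1.53, SE 0.13). The Activin antagonist gene Fst rose from 7.32 ± 1.1 to 42.9 ± 5.2 CPM (2.55, SE 0.17), and Ptk6 rose (3.09, SE 0.64), though not without S5 library 2 (adjusted p = 0.072). Of the Nodal and Activin target genes 9 fell (median −1.31; adjusted p = 9.1e-07 with an estimated correlation), and 5 pluripotency genes fell. Cer1 did not pass with DESeq2 (adjusted p = 0.83), and Otx2 fell short of the fold threshold against the other 3 S5 omission groups (−0.97). In all 102 genes rose and 179 fell. BMP4 was left out to ask for the part of BMP signalling. Hspa1b (−2.61, SE 0.34), Hspa1a (−2.56, SE 0.41), Jun (−1.32, SE 0.24) and Wnt11 (−1.19, SE 0.24) fell, but Hspa1b stood at 61.7 ± 60 CPM in the full medium, where 1 library held most of it. Gata4 stood at 141 ± 8.1 against 232 ± 57 CPM (−0.72, SE 0.15), below the fold threshold, and no endoderm gene rose or fell (1 fell adjusted over the list alone), though the list was called downward with a median of −0.56 (adjusted p = 0.0059 with an estimated correlation). The endoderm list was called upward instead by camera against the other 3 S5 omission groups (adjusted p = 0.017 with an estimated correlation). Those groups differ in endoderm genes themselves, with Gata4 at 56 CPM without FGF4, 96.1 without XAV939 and 223 without Activin A. The upward call can therefore not tell whether the downward call comes from BMP4 or from the S5 libraries. The BMP target list was not called. In all 4 genes rose and 10 fell, 14 together, and 2241 had an unadjusted p below 0.05. Without S5 library 1 the count was 108, without S5 library 2 it was 0, and without either BMP4 omission library it was 1. DESeq2 gave 22, edgeR's newer option 32, no low-count filter 36 and the S5 libraries fitted alone 0. Against the other 3 S5 omission groups 68 genes passed, and Hspa1b (0.15), Hspa1a (0.22), Jun (0.33), Wnt11 (0.08) and Gata4 (0.41) had the opposite sign. For Gata4 that sign may come from its low level without FGF4 and without XAV939. Hspa1b was −0.91 without S5 library 2 and passed without either BMP4 omission library. Hspa1a (−0.83), Jun (−0.34) and Wnt11 (−0.64) did not pass without S5 library 2, nor without BMP4 omission library 1 (adjusted p = 0.061, 0.15 and 0.28) or 2 (adjusted p = 0.15, 0.16 and 0.21).

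FGF4 was left out at S5 to ask for the part of FGF signalling. Lama1 fell from 741 ± 49 to 101 ± 15 CPM (−2.88, SE 0.19), Wnt6 (−3.26, SE 0.22), Aqp8 (−3.19, SE 0.3) and Hspa1b (−2.89, SE 0.34) fell, Gata6 fell from 120 ± 21 to 26.7 ± 2.9 CPM (−2.17, SE 0.13) and Sox17 fell to 6 ± 0.31 CPM (−2.12, SE 0.18). Of the endoderm genes 24 fell and 1 rose (median −1.56; adjusted p = 2.3e-05 with an estimated correlation), Sparc (−1.94, SE 0.11) included, and 17 trophectoderm genes fell (18 adjusted over the list alone), Cited2 (−1.45, SE 0.11) and Krt18 (−1.51, SE 0.12) included. Esrrb fell to 18.5 ± 2.2 CPM (−2.49, SE 0.13) with 10 pluripotency genes, and Wnt8a rose to 34.4 ± 1.1 CPM (2.73, SE 0.18). Of the FGF and ERK target genes 3 fell, Dusp4 (−1.24, SE 0.11) included, with a list median of −0.03 and an adjusted p = 0.021 with an estimated correlation. Among feeder fibroblast genes 1 rose, and the list call was lost, adjusted p = 0.4 with an estimated correlation. In all 531 genes rose and 635 fell, 1166 together or 697 against the other 3 S5 omission groups, where neither Krt18 (−0.96) nor Dusp4 (−0.71) passed. XAV939, a tankyrase inhibitor that lowers Wnt signalling, was left out to ask for the part of Wnt inhibition. Wnt8a rose (1.60, SE 0.18), Zscan4d rose from 21.1 ± 1.8 to 62.7 ± 0.55 CPM (1.57, SE 0.16) and Zscan4c from 31.7 ± 1.3 to 88.5 ± 0.6 CPM (1.48, SE 0.14), and 27 of the 2C-like genes rose (29 adjusted over the list alone; median 1.38). The Wnt target genes T (1.71, SE 0.27) and Cdx1 (1.26, SE 0.21) rose with 5 of the list in all. Gata4 fell to 96.1 ± 21 CPM (−1.27, SE 0.15), Dab2 (−1.06, SE 0.12), Lrp2 (−1.60, SE 0.18), Cer1 (−2.29, SE 0.42) and Afp (−2.05, SE 0.29) fell, as did Hspa1a (−2.64, SE 0.42) and Hspa1b (−2.47, SE 0.34), and 15 endoderm genes fell and 1 rose. In all 283 genes rose and 253 fell, 536 together. Without S5 library 2 the count was 182, without XAV939 omission library 1 it was 310 and without library 2 it was 991, and edgeR's newer option gave 822. Cer1 did not pass with DESeq2 (adjusted p = 0.79). Without S5 library 2 Gata4 stood just short of the fold threshold and Dab2 (−0.85), Hspa1a (−0.92) and Hspa1b (−0.77) did not pass, nor did Dab2 without XAV939 omission library 1 (−0.88). Against the other 3 S5 omission groups the falls of Gata4 (−0.33), Dab2 (−0.39), Lrp2 (−0.49), Cer1 (−0.52) and Afp (−0.60) did not pass, nor did the rises of T (0.78) and Wnt8a (0.03), and Hspa1a (0.11) and Hspa1b (0.33) had the opposite sign. Hspa1b without FGF4 did not pass against those groups either (−0.22).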

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

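The mESC and EPSC responses to the totipotency medium differed in 4678 genes by a test of the difference itself. The responses at passage 25 and after 2 days differed in 2331 genes by the same kind of test. In both cases the compared responses lie in different library sets.

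With 4 libraries the EPSC group was large enough to ask whether a single library stood alone, as a gap to its nearest neighbour over the whole range against Dixon's 95% value for 4 samples. Of 189 named genes tested 18 passed, and chance gives about 1 in 20 groups. The ratio was 1 for Zscan4c, Zscan4e, Zscan4-ps3, Zscan4-ps2, Zscan4a, Zscan4f, Stra6, Stmn4, Abhd12b, Il20ra, Crygd, Aurkc, Csf3r, Habp2, Ttr and Ptk6. It was 0.922 for Tle6 and 0.89 for Fosb. In each gene with a ratio of 1, 3 libraries had no count and 1 library had few, so these ratios come from genes near the floor. The EPSC libraries also span both library sets, and no single library recurred throughout.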

How the results depend on the processing

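The alternatives fixed beforehand changed 1 choice at a time, and all of them were run. A further 6 were chosen after seeing the data: counts of the 46 libraries with separately counted mates halved, genes measured in both sets alone, CHIR and PD0325901 libraries 2 left out together, each omission against the other 3 omission groups of its stage, the mean of the 5 S3 groups in place of S3, and edgeR's newer option without legacy mode. The cause of a shift was not tested unless stated.

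With RLE size factors all 27 counts stayed within 1.5 times their value and the correlation within its SD. The counts that moved further are these. With the 4 EPSC libraries pooled, CHIR went from 4673 to 7564 genes, P25 against 2-day S1 from 2331 to 7517 and S2 against 2-day S1 from 3374 to 8892, and with no set adjustment the last 2 were 8037 and 9393. With halved counts Elvitegravir went from 2 to 0 genes and P38 against P25 from 85 to 145. DESeq2 gave 43 genes for Elvitegravir and 22 in place of 14 for BMP4. The newer edgeR option gave 0 for Elvitegravir, 32 for BMP4 and 822 in place of 536 for XAV939. Without the filter Elvitegravir had 142 genes and BMP4 36, and the correlation of the EPSC and mESC responses went from 0.49 to 0.36. Fitted with their own family alone, Elvitegravir and BMP4 had 0 genes by edgeR, P38 against P25 had 192 and the genes beyond the sum went from 1711 to 490. Without CHIR and PD0325901 libraries 2, Elvitegravir had 0 genes by edgeR and the genes beyond the sum were 870. For Elvitegravir 4529 genes had an unadjusted p below 0.05 as reported, and for BMP4 2241. Against the other 3 omission groups the counts went from 481 to 756 (S2 without 8Br-cAMP), 746 to 2093 (S2 without Birabresib), 583 to 1125 (S2 without CD1530), 1556 to 2891 (S3 without Birabresib), 14 to 68 (BMP4) and 1166 to 697 (FGF4). The list calls fell from 367 to 180 with an estimated correlation.

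The labels give the libraries 1 and 2 of different groups nothing in common but the number. The correlations of library differences within comparisons ran from −0.20 to 0.89, the highest for CHIR and PD0325901, whose libraries 2 deviated together, and it was 0.73 between the S2 groups without Birabresib and without CHIR. No number was therefore read as a pairing. With the replicate block Elvitegravir had 68 genes, and the other 26 counts stayed within 1.5 times.

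Without each library in turn, with the lone sample of a group assumed to vary like the other groups and with the trended dispersion of the full fit, 110 values stayed within 1.5 times (the correlation within its SD) and 24 did not. The ranges were 0 to 1562 for Elvitegravir, 628 to 4657 beyond the sum, 45 to 92 for P38 against P25, 366 to 680 for S2 without Birabresib, 0 to 108 for BMP4 and 182 to 991 for XAV939, and 0.45 to 0.47 for the correlation, which has an SD of 0.015.

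The 381 values of named genes had 4915 alternatives, of which 4784 gave the same call, 107 lost it, 4 gained it and 20 changed sign. With Elvitegravir, Nanog (0.00 as reported) was −0.01 with halved counts, −0.02 with DESeq2 and with RLE, −0.03 without CHIR and PD0325901 libraries 2, and from −0.09 to 0.13 without 1 library, and Zscan4c (0.13) ranged from −0.18 to 0.40 without 1 library. In S2 against 2-day S1, Septin2 was −0.07 and Dlx3 −0.86 with EPSC libraries pooled, and they were −0.07 and −0.86 again with no set adjustment. Csf3r in S3 against S2 was −0.06 with the mean of the 5 S3 groups. Against the other 3 omission groups of S5, Hspa1b (0.15), Hspa1a (0.22), Jun (0.33), Wnt11 (0.08) and Gata4 (0.41) were positive without BMP4, and Hspa1a (0.11) and Hspa1b (0.33) without XAV939. Of the 107 lost calls 51 came from leaving out 1 library and 17 from the other 3 omission groups.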

Other observations

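The test of intron length, and both tests of the S3 libraries, were written before their results were seen, while the tests of overlap, of ribosomal genes, and of the CHIR and PD0325901 libraries were chosen after.

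In the first library set 473 genes had no count in any of 12 libraries although they stood above 1 CPM in all 40 others. Of the 461 with coordinates 100% had nearly all of their exonic bases inside another gene, against 1.6% of 10778 other genes, as counting over whole gene bodies with overlapping genes dropped would give. Such counting would also take in intron reads, and the tables argue against these, since the ratio of EPSC libraries 1 and 2 to 3 and 4 had a Spearman rho of 0.008 with intron length over 6781 genes. The overlap and the missing trend point in different directions, and the share of intron reads in these libraries, which would decide between them, is not in the tables. Loss of expression needs 0 ribosomal protein genes among them and 3 were there (Rpl13, Rpl35 and Rpl35a, at 1100, 219 and 262 CPM in the second set), which argues against it for those genes, while the bound of 5 set to exclude it for the whole set was not met. Loss of expression would not by itself pick out genes inside other genes. The 100% against 1.6% therefore argues against it for the 461 genes with coordinates, and it stays open for those without. How the first set was counted stays open.

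The S3 libraries stood apart from all 4 S3 omission groups, with 42 genes risen and 4 fallen in every omission. Independent lists would share 0.047 genes, but lists with a shared reference are not independent. Across 20 simulations of unchanged groups against that reference, at most 0 genes were common. Those groups held no changed genes, so the 0 cannot show how many genes lists of real changes would share. Length and GC bias explained 0.3% of the shift. In 78.3% of the 46 genes the S3 libraries lay outside the range of all 28 other libraries of S2, S3 and S5, and 32.6% had S3 nearer to S2. This decides nothing about a common state reached by loss of any agent, because the genes were chosen for S3 lying apart from the omission groups. The S2 libraries with the full medium had every agent for 1 day. A state that needs every agent on the second day as well would still lie outside them, so that explanation stays open. Mitochondrial genes took 0.78% to 0.9% of counts in the S3 libraries and 1.58% to 3.43% in the others, so a difference in sample handling or a mislabelled sample may play a part and stays open.

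Libraries 2 of CHIR and PD0325901 deviated from libraries 1 together, with a correlation of 0.89 between the differences. Length and GC bias explained 40% of the difference in CHIR and 25.1% in PD0325901, and pseudogenes took 0.77% and 0.89% of their counts against at most 0.7% in the other 10 libraries, so library preparation is a candidate explanation. No biological explanation was tested, because the libraries of a group share their treatment. A difference between cultures stays open, and the comparisons with CHIR depend on these libraries, with 870 genes beyond the sum without both and 1711 with them.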
